A study of Mus musculus with 18 samples.

How the data were processed

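Array comparative genomic hybridisation measures, at each probe, how much DNA of one animal binds relative to the DNA of another animal labelled with a second dye. The series covers 9 mice of 1 family, all per the labels of strain C57BL/6 and sampled from tail tissue: a sire, a dam and 7 progeny. Each mouse was hybridised on 2 arrays, once in Cy3 and once in Cy5, against DNA of 1 reference male, which makes 18 arrays. Per the series design text, these parents were not irradiated, and the array is a second-round array whose probes were set densely around positions that a first, genome-wide array of the same family had picked out. The probes are therefore not a random sample of the genome. The copy number PCR that the design text names as a last step is not analysed here. The sample labels carry the dose rate of the series title, 0.05 mGy per day over 400 days, as the name of the family.

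Per the file headers, the scanner files were made with Agilent Feature Extraction 12.1.0.3, and probe positions refer to the mouse build mm9. The deposited intensity columns (processed signals of both channels) were background-subtracted, detrended and scaled by 1 linear dye factor per channel, per the file headers. The deposited log10 ratio of Cy5 over Cy3 equalled the ratio of the processed signals within 0.001 on the log2 scale at 99.9% or more of the probe spots of every array. The authors' value table of the whole series holds log2 ratios of the reference over the mouse in every column, as found by setting each column against its scanner file, with an absolute correlation of 0.949 to 1.00. Its column medians lay between -0.0026 and 0.016, and a further correction that it contains is of unstated kind. Its direction is opposite to the one used here.

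Each array has 145014 spots, of which 138451 are probe spots. They hold 134389 different probes of 45 to 60 bases, 134338 of them on autosomes, 48 on the X chromosome and 3 on the Y chromosome. Median signals lay between 1010 and 1054 in the green and between 1011 and 1041 in the red channel, and 99.8% to 99.9% of probe spots were well above background in both channels. No probe spot was saturated. The number of arrays limits the precision.

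Arrays of the same dye orientation correlated with r of 0.101 to 0.795 over 72 pairs (across probes), none of them below 0. Log2 ratios of mouse over reference were computed from the processed signals, turned by the dye labels, and centred on the autosomal median of each array. Control spots and spots marked as non-uniform or population outliers (0.0621% to 0.203% of probe spots) were left out, spots of 1 probe were averaged, and both arrays of a mouse were averaged. No loess or quantile normalization was applied. Errors are the SD over the 2 arrays of a mouse, which share 1 DNA sample and therefore measure technical spread.

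Aberrant intervals were sought with a scan of neighbouring probes. The statistic was the absolute sum of log2 ratios divided by the noise SD and the square root of the number of probes. An interval needed a statistic of at least 6, at least 3 probes with gaps of at most 100 kb, and a mean of at least 0.25 away from 0 in the same direction in both dye orientations. An interval could hold up to 2000 probes. This limit was raised from 500 after a long interval on chromosome 4 had been seen to reach it. Intervals of all mice that shared a probe were merged into loci, and each mouse was given a state (gain, loss or neither) at the interval with the highest statistic. The scan was also run on the halved difference between both orientations, less its mean over the mice, as a guide to array noise. It kept the limits of 6, 3 probes and 0.25, but had no minimum in each orientation. Effects common to both arrays of a mouse cancel in it, so its count is not the number of called intervals that noise made. Loci at which a parent had 1 direction and progeny only the opposite fell into none of the classes set beforehand and were counted apart.

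Probe tests and locus tests used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment. Progeny were compared with parents per probe on 1 mean per mouse, and the 9 mice were compared with 0, the level of the reference. Each progeny was compared with each parent at every locus over all 18 arrays with a dye term. The p-values of the locus test measure the spread between arrays of the same DNA, and the loci were picked for their size. Transmission was given per locus with exact binomial (Clopper-Pearson) 95% intervals. The exact binomial test of all loci against 50%, set beforehand, presumes inherited changes and independent readings. Most of the loci were short and followed a trend over the mice, so the test does not apply to them and its p is not given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

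The steps were tested on simulated data. The interval scan was run on 134389 probes with the median noise SD of single arrays (0.115). Intervals of 3 probes with a change of 0.5 were recovered in 99.5% of cases and with a change of 0.3 in 53.3%, and a track without changes gave 0 intervals. The noise was simulated as independent between probes. For progeny against parents, 86% of 200 simulated probes changed by 0.5 in every progeny were recovered, with 15 false calls among 134338 probes. For all mice against the reference, 98.5% of 200 probes changed by 0.5 in every mouse were recovered, with 0 false calls. In the locus comparison, 100% of 50 loci changed by 0.5 were recovered, with 3 false calls.

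The arrays lay on 5 slides and were scanned on 3 days. Both parents were on a slide of their own, progeny 1 and 2, progeny 3 and 4, and progeny 5 and 6 shared a slide each, and progeny 7 had its own. The parents were scanned on the same day as progeny 1 and progeny 2. Slide and parental role cannot be separated by a fixed term, so slide was entered as a random block, and scan day as a fixed block.

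The tests, the loci to be named and 27 of the 36 alternatives were set before the data were examined. Chosen after seeing the data were 9 alternatives, the limit of 2000 probes, the limit of 12 probes for a short interval, the length of 3 kb, the tiled blocks (at least 20 probes with gaps of at most 2 kb), the interval on chromosome 8 and the rules for single probes and for runs of dim probes. Named loci were, for each family pattern, up to 10 with the highest statistic. Alternatives were normexp background correction with an offset of 50 (on median spot signals and median background, as mean spot signals were not used here), the authors' value table, keeping outlier spots, leaving out dim probes, centring on the mode, removing the reference, other limits of the scan, other merging, each dye orientation alone, each mouse left out, and replicated probes left out. Those added were intervals of at least 3 kb, a lowess on probe brightness removed, progeny 3 and progeny 7 left out (the mice with the most intervals), scan day as a block, the scan day of the parents alone, at most 500 probes per interval, and removal of the first 1, 2 or 3 principal components of the probes outside called intervals. Intervals of the scans with a trend removed were matched to the 661 by a shared probe in the same mouse and direction, a step also added after the results were seen. Correction for GC content and the gene lists fixed beforehand were not run, because probe sequences and a gene annotation on mm9 were not used here, and for the same reason loci are given by position without gene names.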

Results

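The family comprised a sire, a dam and 7 progeny, and each mouse was compared with 1 reference male on 2 dye-swapped arrays. Values are log2 ratios of mouse over reference, so that a gain is positive. The authors' value table has the opposite sign. On the 48 X chromosome probes, the dam lay at 0.96 ± 0.06 (SD, n = 2 arrays) and the sire at -0.01 ± 0.04, which set the scale of the arrays for 2 copies against 1. Progeny 3 to progeny 7 lay between 0.95 and 0.98 on the X chromosome, progeny 1 at 0.01 and progeny 2 at 0.00. On the 3 Y chromosome probes, the dam lay at -3.94 ± 0.13 and progeny 3 to progeny 7 between -4.17 and -3.49, while the sire, progeny 1 and progeny 2 lay between -0.03 and 0.00. The labels do not give the sex of the progeny.

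The series asked whether DNA copy number of progeny departs from that of their parents, and this family served as the non-irradiated one. The interval with the most probes was a gain on chromosome 4, from 101120562 to 101270967 (mm9), carried by the sire and progeny 7. Over its 657 probes, the sire lay at 0.55 ± 0.03 (SD, n = 2 arrays), a 1.47-fold signal, and progeny 7 at 0.51 ± 0.03, a 1.42-fold signal. The dam and the other 6 progeny lay between -0.01 and 0.00. Progeny 7 differed from the sire by -0.05 (limma, adjusted p = 0.473) and exceeded the dam by 0.52 (adjusted p = 2.65e-06). Each of the other 6 progeny lay lower than the sire by 0.55 to 0.56, with adjusted p-values of 1.48e-06 to 1.67e-06. The interval began at the outermost probe of a tiled block, with 163480 bp to the nearest probe on its left, so that its left end is not bounded more closely. On its right, the tiled block went on from 101270969 to 101271189 outside the interval.

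**Figure D1:**
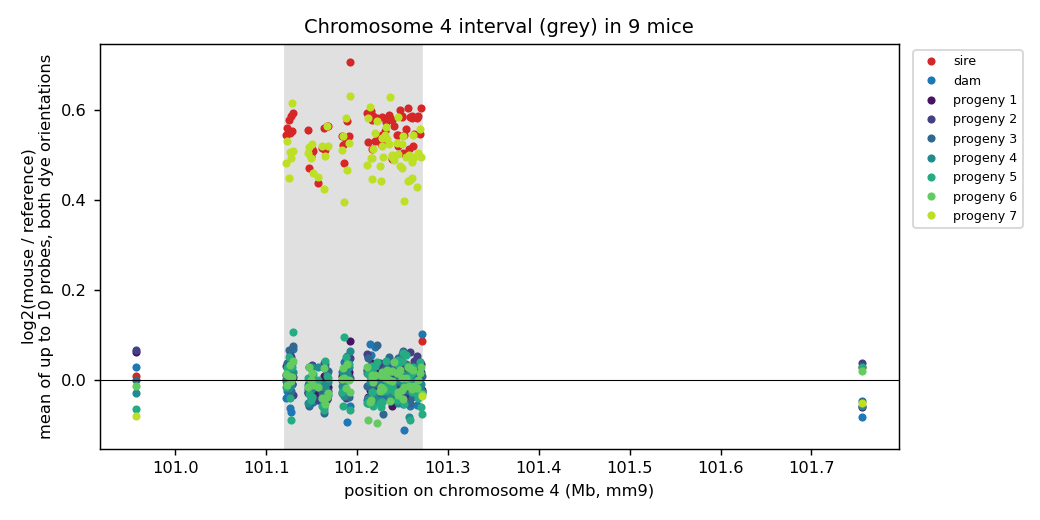
Log2 ratio of mouse over reference against position on chromosome 4 in Mb (mm9) for the 9 mice, where each point is the mean of up to 10 neighbouring probes over both dye orientations. Inside the grey interval the sire (mean 0.55) and progeny 7 (mean 0.51) lie apart from the other 7 mice, whose means lie between -0.01 and 0.00.

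A loss on chromosome 3, from 25421508 to 25435605, was read by 9 probes. The dam lay at -1.59 ± 0.02 (SD, n = 2 arrays), and progeny 3 to progeny 7 lay between -1.62 and -1.39, whereas the sire, progeny 1 and progeny 2 lay between -0.01 and 0.03. Progeny 5 was higher than the dam by 0.19 (limma, adjusted p = 0.0115) and progeny 6 by 0.15 (adjusted p = 0.0463), and these mice shared a slide. Progeny 3, progeny 4 and progeny 7 did not pass the test against the dam, with adjusted p-values of 0.421 to 0.815. All 6 mice with the loss had an X chromosome value of at least 0.95 and a Y chromosome value of at most -3.49. On chromosome 8, from 102237046 to 102244359, 39 probes lay at 0.30 ± 0.15 in the dam and at 0.23 to 0.28 in progeny 3 to progeny 7. The sire, progeny 1 and progeny 2 lay between -0.04 and 0.00 there. This interval was singled out after its values were seen, and the dam and these progeny missed the minimum of 0.25 in 1 of the 2 orientations.

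**Figure D2:**
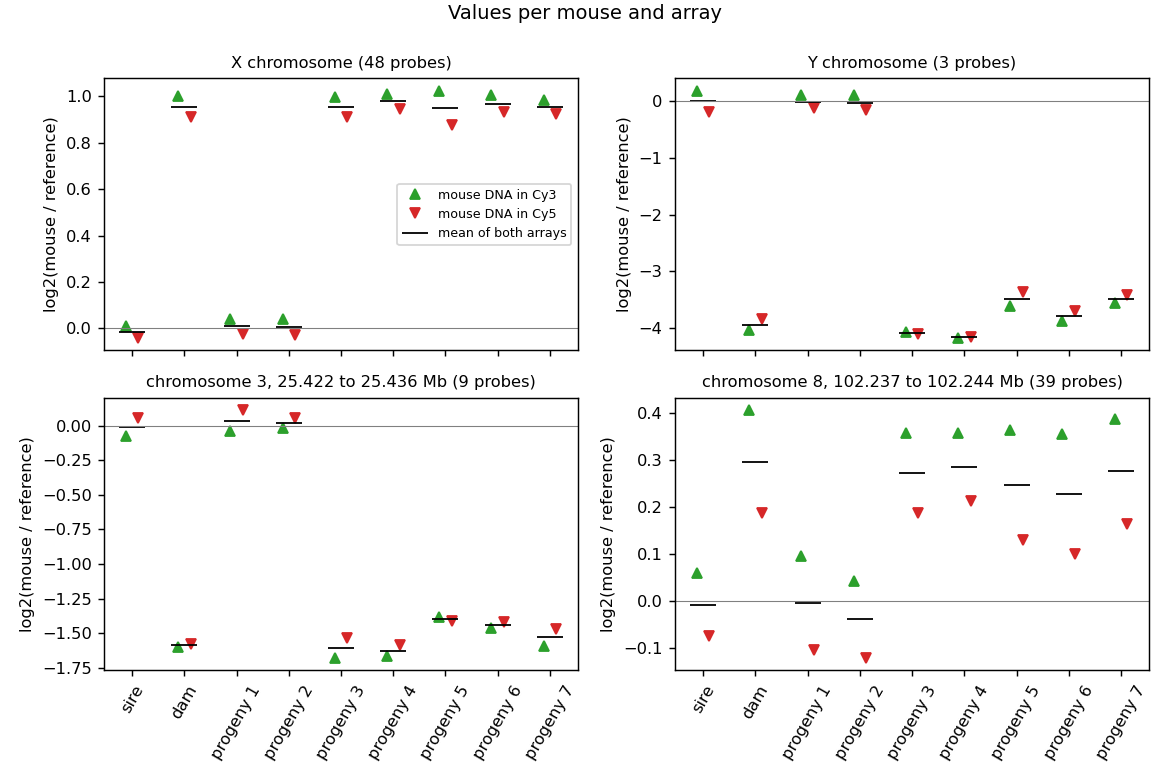
Log2 ratio of mouse over reference in each of the 9 mice for the X chromosome, the Y chromosome, the chromosome 3 interval and the chromosome 8 interval, with triangles for the 2 arrays of a mouse and a bar for their mean. The dam and progeny 3 to progeny 7 lie apart from the sire, progeny 1 and progeny 2 in all 4 panels.

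Both intervals with a state in all 9 mice lay on chromosome 14. From 53710490 to 53764803, the means of the 9 mice over 40 probes lay between -0.84 and -0.77, with a mean of -0.80 ± 0.03 (SD, n = 9 mice). From 53961688 to 54386879, the means over 158 probes lay between -0.36 and -0.31, with a mean of -0.33 ± 0.02 (SD, n = 9 mice). The level was uneven inside it, as the mean over the mice ran from -0.62 to 0.04 over 29 bins of 5 neighbouring probes, and from -0.62 to -0.16 over the 11 bins whose probes were all well above background. A tiled block of 27 probes inside it had means between -0.29 and -0.20. Between the ends of the longer interval, 40 of 159 probes missed being well above background on at least 1 array, and 16 were well above it in at most 2 of 36 readings. A shorter stretch next to them, from 53424325 to 53439569, held 6 probes at -0.35 to -0.26 and had a state in the sire and 6 progeny. In the probe test of all 9 mice against the reference, 136 of 134085 probes passed (limma, adjusted p under 0.05 and at least 0.25 away from 0), 134 of them lower and 2 higher. Of these, 131 lay on chromosome 14 between 53424325 and 54386879. Of the 5 others, 4 were single probes, higher on chromosome 13 from 95707465 (mean 1.40, adjusted p = 0.00332) and lower on chromosome 1 from 137455681, chromosome 7 from 36765289 and chromosome 19 from 35476489 (-0.30 to -0.26). The chromosome 13 probe was not at 1 level, as it ran from 0.11 in the dam to 2.48 in the sire. The fifth, on chromosome 8 from 102238901 (mean 0.27), lay in the 39-probe interval above, at 0.30 to 0.42 in the dam and progeny 3 to progeny 7 and at 0.03 to 0.10 in the sire, progeny 1 and progeny 2. With 1 dye orientation alone the counts were 5099 and 5179, where dye effects do not cancel. The reference is 1 animal, so its own spread is not part of these tests.

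**Figure D3:**
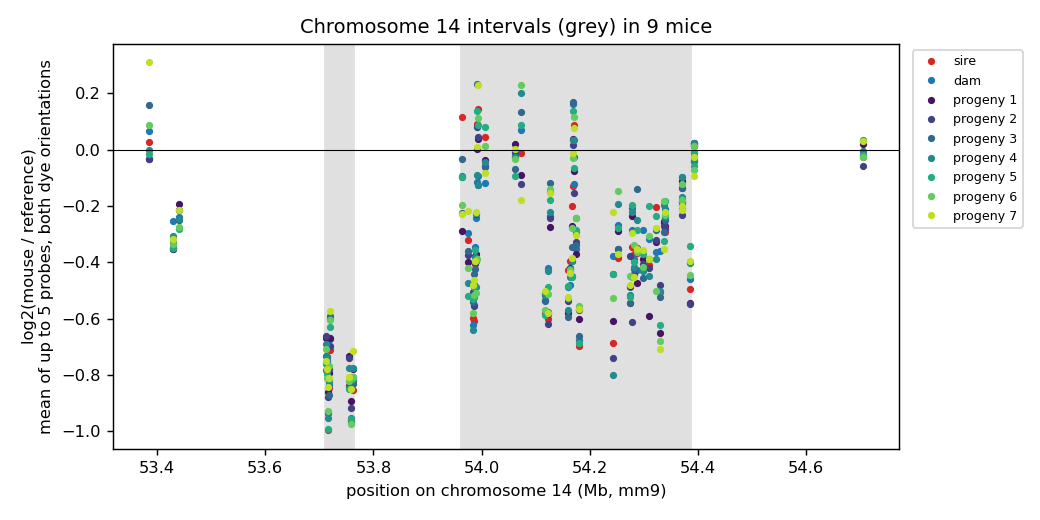
Log2 ratio of mouse over reference against position on chromosome 14 in Mb (mm9) for the 9 mice, where each point is the mean of up to 5 neighbouring probes over both dye orientations and grey marks the intervals with a state in all 9 mice. The interval means of the mice lie together, at a mean of -0.80 in the left and -0.33 in the right interval. Single points of the right interval part most widely from 53991932, where none of the 5 probes was well above background on every array.

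Beyond these stretches the calls were short. The scan gave 661 intervals over the 9 mice, 579 gains and 82 losses, of which 404 spanned 3 probes and 640 at most 12 probes. Their number differed widely between mice, with 357 in progeny 7, 158 in progeny 3, 48 in progeny 5, 38 in the dam and 31 in progeny 2. The sire had 12, progeny 6 had 8, progeny 4 had 5 and progeny 1 had 4. The scan of the difference between orientations gave 59 intervals in all: 5 in progeny 7, 7 in progeny 3, 12 in progeny 5, 12 in the dam, 2 in progeny 2, 6 in the sire, 3 in progeny 4 and 1 in progeny 1. In progeny 6 it gave 11, where the main scan called 8. The scan of the difference had no minimum in each orientation, and without that minimum 18 intervals were called in progeny 6. The order of the mice depended on the setting. With the first component over the mice removed, progeny 7 had 1 interval and the dam and progeny 3 had 27 each. That removal also altered the long regions. Without the Cy5 orientation the dam had 297 and progeny 7 had 217, and without the Cy3 orientation progeny 3 had 261 and progeny 7 had 189. Without progeny 3 and progeny 7 the total was 146, with at least 5 probes per interval it was 129, and with no minimum in each orientation it was 1204. Only 35 intervals spanned at least 3 kb, and they formed 6 loci. Among 2602 tiled blocks of at least 20 probes, 9 had a mean at least 0.25 away from 0 in both orientations in any mouse, 7 of them in the chromosome 4 gain and 2 in the chromosome 14 stretches, of which 1 had a state in all 9 mice and the other in 1 mouse.

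**Figure D4:**
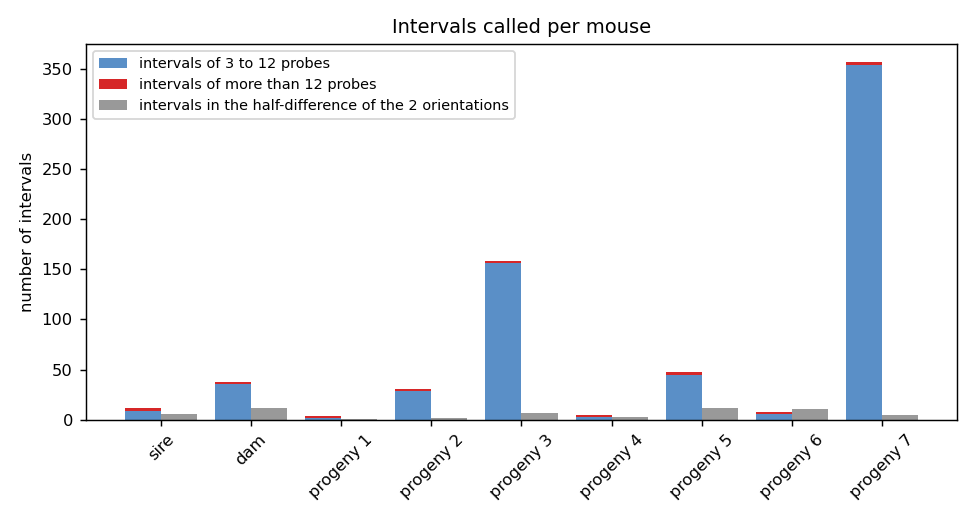
Number of called intervals in each of the 9 mice, split into intervals of 3 to 12 probes and longer ones. Grey bars give the number found by the scan of the difference between the dye orientations, in which effects common to both arrays cancel. That scan had no minimum in each orientation, unlike the called intervals. Progeny 7 with 357 and progeny 3 with 158 intervals stand above the other mice, whose counts lie between 4 and 48.

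Merged over mice, the intervals formed 478 loci. A state in 1 progeny only was found at 262 loci and a state in 2 or more progeny but no parent at 165. These counts were 50 and 10 with at least 5 probes, and 57 and 12 with a mean of at least 0.4. After the first component over the mice was removed they were 15 and 0. That step also left 0 loci alike in all 9 mice and turned the chromosome 3 loss of progeny 7 positive. The fall after it therefore cannot by itself tell a trend from real differences between mice. At loci of at most 12 probes, the mice without a state followed the first component of single probes outside the loci, with a median r of 0.854 over 473 loci. Each r was given the sign relative to that over all 9 mice, which moves the median toward positive values. A further 26 loci were shared by a parent and progeny, 18 had a state in parents only, 2 were alike in all 9 mice, and at 5 a parent had 1 direction and progeny only the opposite. Among loci of at least 3 kb, 0 had a state in 1 progeny only, and 1 had a state in 2 progeny and no parent. It lay on chromosome 14 from 82942213 to 82949047, where 3 probes lay at 0.35 ± 0.05 (SD, n = 2 arrays) in progeny 3 and 0.45 ± 0.005 in progeny 7. The other mice, without a state, were spread widely there. Progeny 4 lay at 0.18, progeny 5 at 0.17, the dam at 0.01 and progeny 6 at -0.002. The sire lay at -0.21, progeny 1 at -0.22 and progeny 2 at -0.29. Without progeny 3 and progeny 7, the loci with a state in 1 progeny only numbered 51 and those in 2 or more progeny 5. A state is relative to the reference male, so a state seen only in progeny is not by itself a new change. The 10 loci of 1 progeny only with the highest statistic spanned 87 to 992 bp with absolute values of 0.28 to 0.58, led by chromosome 15 from 36717850 to 36718329, where progeny 3 lay at 0.34 ± 0.11 (SD, n = 2 arrays) and progeny 7, without a call, at 0.28 ± 0.12. At 3 of these 10, on chromosome 2 from 100379499 and on chromosome 7 from 47257219 and from 47258786, at least 50% of the probes missed being well above background on at least 1 array. Of the loci in 2 or more progeny, the one with the highest statistic lay on chromosome 10 from 60753474 to 60753604, with gains in progeny 3 (0.60 ± 0.21) and progeny 7 (0.70 ± 0.13) and a loss in progeny 2 (-0.53 ± 0.38). The sire (-0.34 ± 0.19) and progeny 1 (-0.32 ± 0.10) were also low there, without a state. The highest among parents only lay on chromosome 3 from 151560903 to 151561787, where the dam was at 0.45 ± 0.03. Progeny 5 (0.27 ± 0.19) and progeny 7 (0.23 ± 0.03) were also raised there, without a state. Of the 10 shared loci with the highest statistic, 9 had a state in the dam, 9 in progeny 5 and 10 in progeny 7. After the chromosome 4 and chromosome 3 intervals these were led by chromosome 1 from 189508910 to 189509703 and chromosome 5 from 128284424 to 128285252. All those after the chromosome 4 and chromosome 3 intervals had gains in the dam, progeny 5 and progeny 7 and in no other mouse. Progeny 3 lay below 0 at each of these loci, from -0.33 to -0.09, and had a loss at the one on chromosome 9 from 90729987. These loci lay on several chromosomes with 1 pattern of gains over the mice, so they are not separate cases of sharing between parent and progeny.

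Exactly 1 parent had a state at 49 loci, the sire at 11 and the dam at 38. The parent's state was found in 48 of 343 progeny readings, or 13.99%, and in 6.12% with a minimum of 0.4 in each orientation. All but 3 of these loci were shorter than 3 kb, and the share at such loci is not a measure of transmission. The chromosome 4 gain of the sire was found in 1 of 7 progeny (14.3%, exact 95% interval 0.361% to 57.9%). The chromosome 3 loss of the dam was found in 5 of 7 (71.4%, exact 95% interval 29.0% to 96.3%). That loss went with a low Y signal in 9 of 9 mice, so its share is not a measure of transmission either. The loss on chromosome 14 from 53424325 was counted as the sire's and found in 6 of 7 (85.7%, exact 95% interval 42.1% to 99.6%), but the dam lay at -0.26 there without a state.

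No probe passed the test between the 7 progeny and the 2 parents. The test compares group means, so a change in 1 progeny, or one passed to only some of them, can go unseen. No probe of the chromosome 4 gain or of the chromosome 3 loss passed it. The count was 0 of 134085 probes (limma, smallest adjusted p = 0.695), with 9199 probes at an unadjusted p under 0.05. The count stayed 0 with slide as a random block, with scan day as a block, and within the scan day shared by the parents, progeny 1 and progeny 2. That last fit compared only 2 progeny with 2 parents, and its recovery was not simulated, so its 0 says little. In the comparison of each progeny with each parent over the 478 loci, 3282 of 6692 tests passed (limma, adjusted p under 0.05), from 21 loci for progeny 1 against the sire to 449 for progeny 7 against the sire. Without the dye term 2073 passed.

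Over all autosomal probes, the 2 orientations of a mouse correlated with r between -0.59 and 0.15 (median -0.32, across probes, which are not independent replicates). Arrays of different mice with the same dye orientation correlated with r of 0.101 to 0.795. Over the probes of called intervals, the 2 orientations of a mouse correlated with r between 0.34 and 0.85 (median 0.68). Those probes were picked for the same direction in both orientations, which raises r.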

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

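For the values of the 7 progeny, the gap between the highest or the lowest mouse and its nearest neighbour was set against the whole range, in 22 sets of values, and chance alone marks about 1 in 20 such sets. It marked 1, the chromosome 4 gain in progeny 7, at 0.51 against a next highest value of 0.00 among the other 6 progeny. The sire lay at 0.55. Among the progeny, the scan had already called this interval in progeny 7 alone. The mark restates that call, and the chance rate does not apply to it.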

How the results depend on the processing

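Of the 36 alternative settings, 9 were chosen after seeing the data: intervals of at least 3 kb, the brightness trend, progeny 3 and progeny 7 left out, both fits by scan day, the cap of 500 probes, and removal of 1, 2 or 3 components. The test of progeny against parents gave 0 probes under each of its alternatives. The test against the reference gave 118 to 139 probes, apart from 5099 and 5179 with 1 dye orientation alone. With each mouse left out in turn it gave 129 to 139. Of 312 values of the named regions under alternatives, 188 moved by less than the SD of their 2 arrays, 102 moved further without changing sign and 22 changed sign. The locus differences fell from 3282 to 2073 without the dye term. No paired analysis by replicate number was run, because all progeny have the same sire and dam. Correction for GC content and the gene lists were not run. Few spots were limited by signal, since at least 99.8% were well above background. Where no cause is named, the cause was not tested.

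Counts of intervals and loci depended on the limits of the scan. With at least 5 probes, by construction fewer, there were 129 intervals and 81 loci: 14 shared by parent and progeny, 5 in parents only, 50 in 1 progeny only, 10 in 2 or more progeny and 0 with parent and progeny in opposite directions. With a mean of at least 0.4 there were 118 intervals and 91 loci: 1 alike in all mice, 4 shared, 57 in 1 progeny only, 12 in 2 or more progeny and 0 opposite. Without a minimum in each orientation there were 1204 intervals and 806 loci, 69 shared and 381 in 2 or more progeny. With a statistic of at least 8, 158 loci lay in 1 progeny only. Intervals of at least 3 kb numbered 35 in 6 loci: 3 shared, 1 in 2 or more progeny, and 0 each in parents only, in 1 progeny only and opposite. Without a gap limit 1 locus was alike in all mice. The share of progeny readings with the state of the 1 aberrant parent, 13.99%, lay at 57.1% at the 3 loci of at least 3 kb (12 of 21 readings), on the other side of 50%. Of these 12, 6 came from the chromosome 14 loss from 53424325, where all 9 mice lay between -0.35 and -0.26, and 5 from the chromosome 3 loss, which went with a low Y signal in 9 of 9 mice, so that this share is not a measure of transmission.

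Other values also moved counts. Normexp background gave 1 locus alike in all mice and 169 in 1 progeny only, the authors' value table gave 10 in parents only, mode centring gave 3 opposite, and removal of the brightness trend gave 1 alike in all mice. Of the 661 intervals, 432 shared a probe with an interval of the same mouse and direction after that removal, and 120 of its 551 intervals had no such counterpart. With 1 orientation alone, intervals numbered 998 to 1076 and loci 648 to 747. Loci alike in all mice then numbered 5 to 7, shared loci 123 to 329, parents only 4 to 127, 1 progeny only 107 to 144, and 2 or more progeny 175 to 365. Without progeny 3 and progeny 7 there were 146 intervals and 105 loci, 51 in 1 progeny only, 5 in 2 or more progeny and 1 opposite.

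With the first component removed there were 92 intervals, 32 of them without a counterpart among the 661, and 49 loci: 0 alike in all mice, 6 shared, 10 in parents only, 15 in 1 progeny only, 0 in 2 or more progeny and 18 opposite. With 2 components removed there were 61 intervals, 25 without a counterpart, and 35 loci: 0 alike, 2 shared, 0 in parents only, 18 in 1 progeny only, 3 in 2 or more progeny and 12 opposite. With 3 removed there were 35 intervals, 17 without a counterpart, and 21 loci: 0 alike, 4 shared, 3 in parents only, 12 in 1 progeny only, 0 in 2 or more progeny and 2 opposite. By construction a component projects a probe's values on weights of the mice, so the correction also altered the long regions. The chromosome 3 loss turned to 0.16 in progeny 7 with 1 component, to 0.066 with 2 and to 0.092 with 3, and with 3 also to 0.027 in progeny 3 and 0.45 in progeny 5. In progeny 5, the shorter chromosome 14 interval turned to 0.069 with 2 components and 0.50 with 3, and the longer one to 0.028 and 0.21. In the sire they turned to 0.049 and 0.029 with 3 components. The chromosome 4 gain stayed positive, at 0.36 to 0.59 in the sire and 0.35 to 0.39 in progeny 7.

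Subtracting the median over the mice sets a change shared by most mice to about 0 by construction, and gave 0 loci alike in all mice and 10 opposite. The chromosome 3 loss of progeny 5 then lay at 0.011. At the shorter chromosome 14 interval, progeny 1 lay at 0.037, progeny 2 at 0.017, progeny 4 at 0.015, progeny 6 at 0.00083 and progeny 7 at 0.038. At the longer one, the sire lay at 0.0086, the dam at 0.018, progeny 3 at 0.021, progeny 5 at 0.026 and progeny 7 at 0.022.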

Other observations

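The single-probe values and all tests here were chosen after the results were seen, apart from those of the trend shared with single probes and of probe brightness, and related correlations had been seen before these as well. For brightness the limits were set beforehand, and the matching of single intervals was added later in place of a ratio of totals, 551 to 661. On autosomes, 13 probes differed by at least 1 between the parents in both orientations, 7 of them in the chromosome 3 loss. Of the 6 others, 5 were low in the dam and in progeny 3 to progeny 7, at 1 probe each on chromosomes 3 (from 132549431), 5 (from 123598779), 6 (from 104241394), 9 (from 35857910) and 11 (from 112961382). The remaining probe, on chromosome 13 from 95707465 to 95707524, lay at 2.48 ± 0.14 (SD, n = 2 arrays) in the sire and 0.11 ± 0.09 in the dam, and all 7 progeny lay between them, from 1.09 to 1.78. Its 6 nearest probes, at 334 bp or more, lay between -0.24 and 0.34 in every mouse. On chromosome 2, from 100379270 to 100380074, 6 of 7 neighbouring probes were well above background in at most 2 of 36 readings.

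A trend shared with single probes may account for many of the short loci. At loci of at most 12 probes the mice without a state followed the weights of the mice on the first component of 3816 single probes. The median r was 0.854 (quartiles 0.740 and 0.920, 473 loci), where each r was multiplied by the sign of r over all 9 mice. This moves the median toward positive values. The trend does not cover 21 of 474 short loci with an absolute r under 0.5 over the 9 mice, 13 of them with a state in a parent. After the first component was removed, 45 of 640 short intervals had a counterpart in the same mouse and direction. After a lowess on probe brightness was removed, 64.5% of the short intervals had a counterpart, between the limits set for and against brightness. The median value of all short intervals went from 0.35 to 0.33. The 227 without a counterpart went from 0.316 to 0.285, still above the scan minimum of 0.25. These values argue against the removed brightness trend as the source of most of the size of the short intervals. Other effects of brightness stay open. The component correlated with brightness (Spearman -0.49, across probes), and 75.55% of the probes in short intervals were dimmer than the median. Changes of a whole copy in every cell are argued against for most, with a median absolute value of 0.35, but 60 short intervals outside the chromosome 3 loss reached 0.5 and stay open. The argument presumes that the reference has no extra copies at these sites and that their probes respond in full. Neither was tested, so sites with extra copies or weakly responding probes stay open too. What produces the trend shared with single probes was not tested.

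A hypothesis for the chromosome 3 loss is sequence on the Y chromosome that binds the same probes, since the loss and a low Y signal occurred together or were both missing in 9 of 9 mice. An autosomal loss with 1 copy on each chromosome of the sire and the reference is argued against, because each progeny would keep the copy of the sire, and the progeny nearest to 0 lay at -1.39. Unequal copy numbers on the chromosomes of the sire stay open. The probe sequences were not matched to a genome here.

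The chromosome 14 losses could come from the reference animal or from all 9 mice. Differences among the mice, such as a mixture of cells that varies between them, are argued against by an SD over the mice of 0.026 for the mean of the shorter interval and 0.019 for that of the longer one. A higher copy number in the reference cannot be told apart from a loss shared by the family, as the mean of -0.80 was measured against 1 reference animal only. A loss in the same share of cells in every mouse stays open as well.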
